A study of Homo sapiens with 18 samples.

How the data were processed

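Poly(A) RNA and ribosomal RNA were measured in DLD1 cells infected with lentivirus, selected with 10 µg/ml puromycin and carrying a control guide (sgC) or ZNF692 guides 1 (sgZ1) or 3 (sgZ3), 3 libraries per guide and kind, 18 in all. Groups and replicate numbers came from the sample titles. One control poly(A) sample's description names the ribosomal RNA table, and its title and molecule label place it among the poly(A) libraries, where it was kept.

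The deposited poly(A) table holds whole-number counts per gene and library, not normalized, as the authors made them. The deposited ribosomal RNA table holds estimated counts, numbers that need not be whole, for 20 entries of ribosomal RNA references. The submitters' processing notes name STAR 2.5.2b, SAMtools 1.9, HTSeq and DESeq2 and the builds hg38 and GRCh38, with no role or order. The annotation release, the strand setting of counting and the way reads shared by near-identical ribosomal RNA copies were divided are not given in the sources used here. Without strand, reads of a gene and of an antisense partner cannot be told apart. Poly(A) selection leaves out most RNAs without a tail. Separately, the 13 mitochondrially encoded genes had 0 counts in all poly(A) libraries, and the cause of this was not tested.

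Poly(A) counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The table held 47021 genes, 14732 passed filterByExpr, and totals ran from 16044224 to 24535642. Of the tested gene IDs 99.2% were found in GENCODE 29 (GRCh38), which gave coordinates, gene lengths and GC content. TMM factors and robust quasi-likelihood fits over all 9 libraries with the group as the only term gave log2 fold changes, standard errors and Benjamini-Hochberg adjusted p-values, called at a false discovery rate under 0.05. The common biological coefficient of variation was 12.7%. The comparisons were the mean of both guides against sgC, each guide against sgC, and sgZ3 against sgZ1, which tests the difference between guides. The CPM values use TMM-scaled library sizes. Limits from a count of 0 are 3 counts over the group and cover counting error only.

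Before the data were examined, 39 gene lists were fixed by hand, of which 38 had tested members. They cover ribosome biogenesis, ribosomal proteins, the exosome, RNA polymerases I and III, MYC targets, translation factors, tRNA synthetases, stress responses, cell cycle, metabolism, mitochondria, interferon and inflammation, Wnt and differentiation genes, adhesion, mesenchymal, immediate-early, heat-shock, NRF2, snoRNA host, RNA quality and poly(A) selection genes, and markers of fibroblasts, leukocytes, endothelium and embryonic kidney packaging cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation 4 of the 17 calls over both guides held, and 0 of the 10, 12 and 9 calls for sgZ1, sgZ3 and the difference between guides.

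Genes named in the text followed a rule fixed at the same time. It takes ZNF692, the 12 highest and 12 lowest log2 fold changes over both guides among genes called with the same sign by each guide, at a mean of at least 2 CPM and with every sgZ1 and sgZ3 library beyond every sgC library, up to 4 members of each list with the smallest adjusted p, and the 5 highest and 5 lowest differences between guides. It also takes the 10 ribosomal RNA entries with the smallest p. XIST, Y-linked genes and entries without a gene name were passed over. The limit to the first 3 members, and to called lists, was set after the data were seen, and so were the names of genes behind small counts. Of the genes this rule takes, 2 are not reported here and were not replaced.

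Ribosomal RNA entries were tested as log2 shares of each library's total, with a pseudocount of 0.5 counts and two-sided exact permutation tests. For edgeR, an alternative there, estimated counts were rounded to whole numbers.

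The edgeR steps were tested on simulated counts drawn from the sample means with known changes in some of 14496 genes. For both guides against sgC, 44.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, with 8 false calls of 154. In the same comparison camera gave an unadjusted p under 0.05 for 20 of 20 lists of 40 genes raised 1.3-fold. It did so for 0 of 20 unchanged lists. Reported list calls are adjusted over the lists, so these counts do not give their sensitivity. These simulated genes vary independently, and in the real libraries camera called a median of 11 lists in 99 other regroupings of the 9 libraries (1 to 19), so calls at the preset correlation also arise without the real grouping.

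The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, library totals alone, no low-count filter, a mean of at least 10 CPM, a false discovery rate under 0.01, a 2-fold minimum, fits of the compared groups only, the replicate number as a block, fry and estimated correlations for lists, other scales for ribosomal RNA shares, and each library left out. Chosen after seeing the data were a fit without sgZ1 replicate 2 and sgZ3 replicate 3 (7 libraries), a fit without the sgZ1 libraries, offsets that remove each library's trend over gene length and GC, and sums over ribosomal RNA copies. No 2 libraries of a group agreed within sampling noise. Levels of XIST and Y-linked genes were left out.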

Results

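RNA was measured in DLD1, an established human colorectal adenocarcinoma cell line, carrying either a control CRISPR guide (sgC) or 1 of 2 guides against ZNF692, a zinc-finger gene, named sgZ1 and sgZ3. Each guide had 3 poly(A) RNA libraries and 3 libraries counted over ribosomal RNA, 18 libraries in all. The poly(A) table held 47021 genes, of which 18022 had 0 counts in every library and 14732 were tested. Total counts were 19537938, 18146624 and 22111364 for sgC, 20816338, 24535642 and 20004597 for sgZ1, and 16044224, 19577886 and 20613158 for sgZ3 (replicates 1, 2 and 3). The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The design asks which transcripts differ between DLD1 cells and derivatives labelled ZNF692 knockout.

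ZNF692 mRNA was not lower in either group labelled knockout. The gene lies on the minus strand of chromosome 1, from 248850006 to 248859144 (GRCh38, protein coding). Its level was 6.51 ± 0.446 CPM in sgC (SD, n = 3), 10.3 ± 1.01 in the libraries labelled sgZ1 and 7.43 ± 0.988 in those labelled sgZ3. The log2 fold change against sgC was 0.66 (SE 0.14, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0048) for sgZ1 and 0.19 (SE 0.14, adjusted p = 0.32) for sgZ3. Over both guides it was 0.43 (SE 0.12, adjusted p = 0.022), a call that was lost without sgC replicate 1 (adjusted p = 0.056), 2 (0.08) or 3 (0.11) or without sgZ3 replicate 2 (0.051), with library totals alone (0.059) and with gene length and GC offsets (0.081). Small insertions or deletions made by CRISPR need not lower mRNA, so this level does not check the labels, and every direction given here is a direction between libraries labelled sgZ1 or sgZ3 and those labelled sgC. The neighbouring genes SH3BP5L, ZNF672 and PGBD2 did not pass the test in any comparison with sgC.

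Some libraries stood apart from the rest. In the 3 libraries labelled sgZ1, 87 genes were above 2 CPM while all 6 other libraries were below 0.5 CPM, and 0 genes met this rule for sgC or for sgZ3. Among them were MAGEB2, a cancer-testis antigen gene (71.7 to 84.1 CPM), and GTSF1 (57.6 to 72.4 CPM). DKK1, a secreted Wnt inhibitor, stood at 290, 381 and 300 CPM in sgZ1 at 0.268 to 0.682 CPM in sgC and at 0.744, 1.03 and 8.27 CPM in sgZ3. MSH6, a mismatch-repair gene in which DLD1 is known to be deficient, stood at 67.3, 69.6 and 74.8 CPM in sgZ1, at 6.53 to 9.48 CPM in sgC and at 4.4 to 8.53 CPM in sgZ3. A further set of transcripts was shared by sgZ1 replicate 2 and sgZ3 replicate 3. VIM, an intermediate filament gene of mesenchymal cells, was at 22.9 and 21.2 CPM in these libraries and at most at 1.22 CPM in the other 7, and SPARC, a matrix protein gene, was at 64.3 and 66.8 CPM against 3.73 to 5.91 CPM. These genes were chosen after their values were seen.

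**Figure D1:**
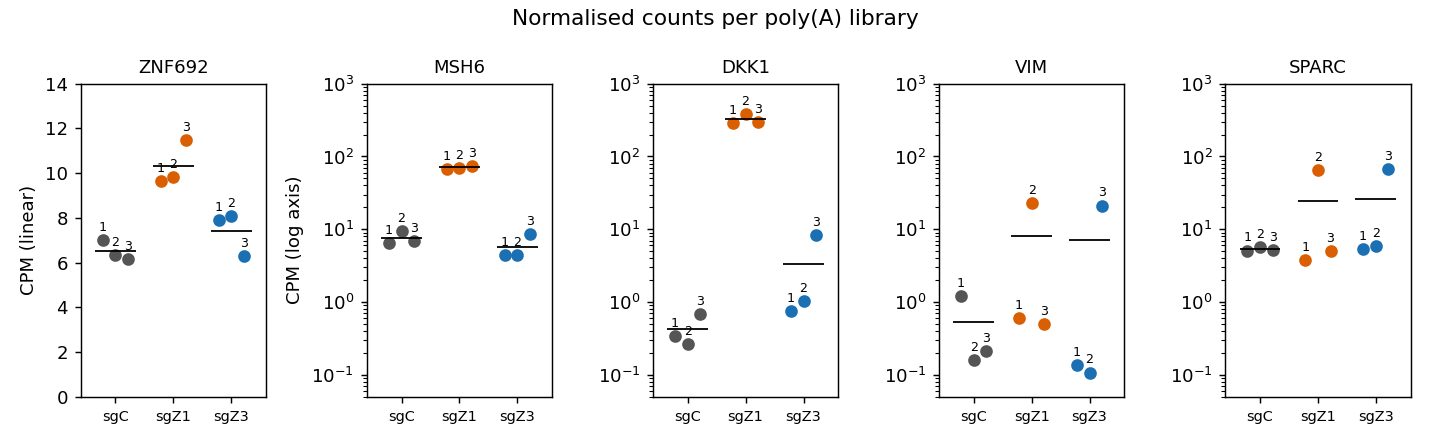
CPM of ZNF692 (linear axis) and of MSH6, DKK1, VIM and SPARC (log axis) in each of the 9 poly(A) libraries, by guide; digits are replicate numbers and black lines are group means. ZNF692 lies between 6.18 and 11.5 CPM, MSH6 and DKK1 are higher in all 3 sgZ1 libraries, and VIM and SPARC are higher in sgZ1 replicate 2 and sgZ3 replicate 3.

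In the mean of both guides against sgC, 4885 of 14732 genes passed a false discovery rate of 0.05 (33.2%), 2734 higher and 2151 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The highest changes among genes called in the same direction by each guide, at a mean of at least 2 CPM and with every sgZ1 and sgZ3 library beyond every sgC library, were in MYL9, a myosin light chain of smooth muscle (log2 fold change 3.22, SE 0.52), CPNE7 (3.16, SE 0.24), CPA4, a carboxypeptidase (3.13, SE 0.85), and HAS3, a hyaluronan synthase (2.83, SE 0.13). PWP2, a small-subunit processome protein (2.44, SE 0.24), HS3ST1, a heparan sulfate sulfotransferase (1.56, SE 0.087), CLEC11A (1.46), STMN3 (1.43), SCO2 (1.42) and SLC1A3, a glutamate transporter (1.41), also rose. So did the noncoding genes ELFN1-AS1 (2.06) and RP11-660L16.2 (1.47), both uncertain where reads of an overlapping gene on the other strand could be counted. The highest adjusted p of these 12 genes was 0.022, that of CPA4. PWP2 counts are also uncertain, since a second annotated gene shares long stretches of its sequence. HAS3 rose from 2.57 ± 0.338 CPM (SD, n = 3) in sgC to 50.5 ± 4.41 in sgZ1 and 6.68 ± 0.76 in sgZ3, and MYL9, CPNE7, PWP2, HS3ST1 and STMN3 also rose more with sgZ1. MYL9 stood at 5.43 CPM in sgZ3 replicate 3 against about 1.3 or less in the other sgZ3 libraries. CPA4 stood at 6.55 CPM in sgZ1 replicate 2 and 4.97 in sgZ3 replicate 3 against at most 1.87 in the others, and did not pass without sgC replicate 1, 2 or 3 (adjusted p = 0.10, 0.086 and 0.11).

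The 12 lowest changes over both guides by the same rule included transporters, metabolic genes and signalling genes. These groups were not tested as such, and the transporter gene SLC1A3 rose (1.41). TXNIP, a thioredoxin-binding inhibitor of glucose uptake, fell from 624 ± 77 CPM (SD, n = 3) in sgC to 278 ± 20.6 in sgZ1 and 151 ± 8.39 in sgZ3. Its log2 fold change was -1.60 (SE 0.085, edgeR quasi-likelihood adjusted p = 1.6e-06). It was lower in 6 of 6 libraries, which the rule required of all 12 genes. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, went from 254 ± 52.4 CPM to 114 ± 29.8 and 88.0 ± 6.11 (-1.34, SE 0.15). SLC22A11, an organic anion transporter (-1.61), SLC16A4, a member of the monocarboxylate transporter family (-1.57), DEPTOR, an inhibitor of mTOR (-1.35), and SLIT1, an axon guidance ligand (-1.34), were also lower. The others were TCP11L2 (-1.52), GPR1 (-1.32), FRMD3 (-1.32), CHRDL1, a BMP antagonist (-1.31), HEPACAM2 (-1.28) and DLX3, a homeobox gene (-1.25). HEPACAM2 had the highest adjusted p of these 12 genes, 0.0069. Without sgC replicate 1 or 3 the number of genes called over both guides was 2201 or 2389. The share of calls that were higher, 56%, was 45.9% with upper-quartile factors, 36.6% with library totals alone, 47.7% with gene length and GC offsets and 46.5% with 7 libraries, without sgZ1 replicate 2 and sgZ3 replicate 3.

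Gene lists of ribosome production rose together over both guides. Of 60 small-subunit biogenesis factors, 40 rose and 1 fell (47 and 1 adjusted over the list alone), with a median log2 fold change of 0.37 (camera adjusted p = 2.5e-11, adjusted p = 0.037 with an estimated correlation). Examples were PWP2 and DHX37, a helicase (0.80, SE 0.088), while the kinase RIOK3 fell (-0.76, SE 0.087). Of 53 large-subunit biogenesis factors, 26 rose and 1 fell (27 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 4.8e-08, adjusted p = 0.037 with an estimated correlation). MRTO4 (0.90, SE 0.088), NOC2L (0.71, SE 0.071) and NOP16 (1.16, SE 0.13) rose and RSL24D1 fell (-0.33). MYC targets of nucleolar and growth type rose in 43 of 58 members and fell in 0 (48 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 2.4e-19, adjusted p = 0.037 with an estimated correlation), among them SLC19A1, a folate carrier (1.02, SE 0.091), and UNG, a uracil glycosylase (0.86, SE 0.085). Of 43 G1/S genes 32 rose and 0 fell (33 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 1.1e-15, adjusted p = 0.12 with an estimated correlation), with FEN1, a flap endonuclease (1.03, SE 0.096), and CCNE1, cyclin E (0.99, SE 0.097). Heat-shock and chaperone genes rose in 16 of 23 and fell in 0 (17 and 0 adjusted over the list alone, median 0.48, camera adjusted p = 8.3e-10, adjusted p = 0.037 with an estimated correlation), with FKBP4 (1.05, SE 0.077), CHORDC1 (0.95, SE 0.11) and DNAJA1 (0.85, SE 0.1). The MYC-target list shares members with each of the other lists in this paragraph, so their calls are not independent. Shared members include MRTO4 and NOP16 with the large-subunit list and UNG with the G1/S list. The transcripts that set the libraries labelled sgZ1 apart, such as MSH6 (67.3 to 74.8 CPM), are part of this contrast through sgZ1.

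Lists of cytosolic and mitochondrial ribosomal proteins and respiratory chain genes also passed over both guides. In sgZ1 alone 40S (0 of 33 higher, camera adjusted p = 0.58), 60S (3 of 47, 0.26), oxidative phosphorylation (3 of 48, 0.67) and translation factor lists (10 of 42, 0.12) did not pass. Over both guides, of 47 tested 60S proteins 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 2e-05, adjusted p = 0.71 with an estimated correlation), with RPL17 (0.53, SE 0.11), RPL6 (0.38, SE 0.079) and RPL36AL (0.47, SE 0.1). Of 33 40S proteins 7 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.0015, adjusted p = 0.71 with an estimated correlation). The call of RPS26 (0.45) was lost without sgC replicate 3 (adjusted p = 0.065). FAU (0.47) and RPS15 (0.40) lost theirs without sgC replicate 1 (0.10 and 0.11), sgC replicate 3 (0.12 and 0.15), sgZ1 replicate 3 (0.051 and 0.05) or sgZ3 replicate 2 (0.051 and 0.057), and RPS15 also without sgZ3 replicate 1 (0.054). These genes have many processed pseudogenes, so their counts are uncertain. Mitochondrial ribosome and translation genes rose in 38 of 70 and fell in 1, MTIF2 (43 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 2.4e-08, adjusted p = 0.66 with an estimated correlation), with MRPS2 (0.62, SE 0.085), MRPL49 (0.77, SE 0.12) and MRPL36 (0.96, SE 0.15). Oxidative phosphorylation genes rose in 15 of 48 and fell in 1, NDUFB5 (15 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0015, adjusted p = 0.71 with an estimated correlation), with NDUFB9 (0.55, SE 0.12), NDUFB10 (0.49, SE 0.11) and CYCS (0.41, SE 0.093, adjusted p = 0.052 without sgC replicate 1). Translation factors rose in 17 of 42 and fell in 1, EIF5 (18 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 0.0025, adjusted p = 0.53 with an estimated correlation), with EIF3B (0.55, SE 0.078) and EIF5A (0.52, SE 0.095).

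RNA polymerase III genes rose in 12 of 27 and fell in 2, POLR3C and SNAPC1 (13 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 0.023, adjusted p = 0.24 with an estimated correlation), with POLR3K (1.02, SE 0.16) and POLR3E (0.54, SE 0.085) among the risers. That list did not pass in sgZ1 (camera adjusted p = 0.20) or sgZ3 (0.058) alone. Cholesterol synthesis and uptake genes rose in 9 of 25 and fell in 1, STARD4 (10 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.018, adjusted p = 0.66 with an estimated correlation). MVD (0.78, SE 0.085) and DHCR7 (0.53, SE 0.078), enzymes of the pathway, rose. In sgZ1 alone the cholesterol list did not pass (camera adjusted p = 0.95). Immediate-early genes rose in 9 of 25 and fell in 1 (11 and 2 adjusted over the list alone, median 0.29, camera adjusted p = 0.036, adjusted p = 0.53 with an estimated correlation). DUSP4, a MAP kinase phosphatase (0.84, SE 0.083), and FOSL1, an AP-1 subunit (1.05, SE 0.12), were higher in the mean of both guides, and SPRED1, an inhibitor of Ras signalling, was lower (-0.49, SE 0.095). DUSP4 did not rise in sgZ3 (13.7 CPM against 16.1 in sgC, adjusted p = 0.074), where the immediate-early list had 3 higher and 5 lower genes (median -0.066, camera adjusted p = 0.36). The immediate-early call was lost without sgC replicate 2 (camera adjusted p = 0.053) or 3 (0.074), without sgZ1 replicate 1 (0.08) or 3 (0.054), and with gene length and GC offsets (0.35). Without sgZ1 replicate 2 and sgZ3 replicate 3, which shared VIM (22.9 and 21.2 CPM), the call of cholesterol genes was lost (camera adjusted p = 0.058).

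Amino-acid stress, epithelial, enterocyte and interferon lists fell in the mean of both guides, and none of these 4 passed in each guide alone. Camera adjusted p in sgZ3 was 0.26 for epithelial, 0.32 for enterocyte and 0.45 for interferon genes, and in sgZ1 0.62 for ATF4 and amino-acid stress genes. Of 32 ATF4 and amino-acid stress genes 12 fell and 6 rose (13 and 7 adjusted over the list alone, median -0.20, camera adjusted p = 0.0018, adjusted p = 0.53 with an estimated correlation). PSAT1, of serine synthesis, fell from 928 ± 38.1 CPM to 618 ± 61.0 in sgZ1 and 467 ± 28.8 in sgZ3 (SD, n = 3), and VLDLR (-1.07, SE 0.12) and the cystine transporter SLC7A11 (-0.94, SE 0.12) fell. Epithelial adhesion and polarity genes fell in 9 of 27 and rose in 1, ESRP1, which was higher in sgZ1 and lower in sgZ3 (10 and 2 adjusted over the list alone, median -0.25, camera adjusted p = 0.027, adjusted p = 0.66 with an estimated correlation), with the tight-junction gene TJP3 (-0.45, SE 0.082), LAMB3 (-0.74, SE 0.16) and DSC2 (-0.67, SE 0.16, adjusted p = 0.053 without sgC replicate 3). Enterocyte and colonocyte genes fell in 4 of 19, LGALS4 (-0.90, SE 0.15), CEACAM1 (-0.78, SE 0.2, adjusted p = 0.061 without sgC replicate 3), CEACAM5 (-1.41) and HNF4A (-0.53), while CA2, a carbonic anhydrase, rose (0.93, SE 0.13). That list had 4 lower and 1 higher adjusted over the list alone (median -0.35, camera adjusted p = 0.027, adjusted p = 0.53 with an estimated correlation), and its call was lost without sgZ1 replicate 2 and sgZ3 replicate 3 (0.066). Interferon-stimulated genes fell in 12 of 35 and rose in 2, ISG15 and HLA-B (12 and 2 adjusted over the list alone, median -0.20, camera adjusted p = 0.032, adjusted p = 0.53 with an estimated correlation), with HERC6 (-0.52, SE 0.085), IFIH1 (-0.51, SE 0.11) and IFIT2 (-0.90, SE 0.2, adjusted p = 0.05 without sgC replicate 1). In sgZ1 replicate 2, which held VIM at 22.9 CPM and SPARC at 64.3 CPM, LAMB3, DSC2, HNF4A and CEACAM1 were lower than in the other sgZ1 libraries (LAMB3 116 against 182 and 219 CPM), while in sgZ3 replicate 3, with VIM at 21.2 CPM, they were higher than in the other sgZ3 libraries (LAMB3 179 against 136 and 158 CPM). Without these 2 libraries the epithelial list passed over both guides (camera adjusted p = 0.0037). The interferon call was lost without sgC replicate 1 (camera adjusted p = 0.059) or 2 (0.071), sgZ1 replicate 1 (0.14) or 3 (0.054), or sgZ3 replicate 1 (0.057).

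**Figure D2:**
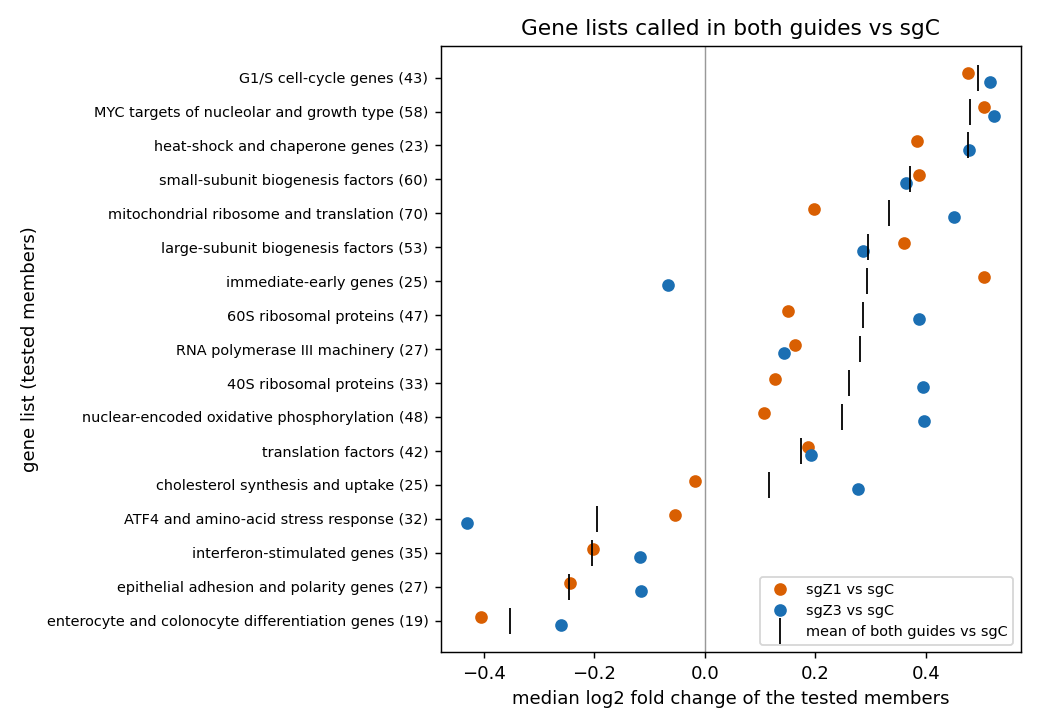
Median log2 fold change against sgC of each gene list called over both guides, for sgZ1, for sgZ3 and for the mean of both guides. The medians over both guides run from -0.35 for enterocyte and colonocyte genes to 0.49 for G1/S genes.

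The other 21 tested lists did not pass camera's test over both guides. Camera adjusted p was 0.16 for the RNA exosome (9 higher and 3 lower of 24, 9 and 4 adjusted over the list alone), 0.11 for RNA polymerase I and rDNA transcription (8 and 3 of 24, and 8 and 3) and 0.51 for aminoacyl-tRNA synthetases (6 and 9 of 23, and 7 and 9). It was 0.081 for glycolysis (10 higher and 1 lower, PDK1, of 23; 11 and 2 adjusted over the list alone), 0.53 for gluconeogenesis and glucose-6-phosphate metabolism (2 and 3 of 11, and 2 and 3), 0.98 for fatty-acid synthesis (4 and 2 of 16, and 4 and 2) and 0.11 for hypoxia (3 and 7 of 21, and 5 and 7). The unfolded protein response gave 0.63 (8 and 6 of 25, and 8 and 7), p53 targets 0.99 (6 and 4 of 28, and 7 and 4), G2/M genes 0.55 (9 and 8 of 48, and 9 and 10), NRF2 targets 0.93 (3 and 3 of 22, and 3 and 3) and NF-kappaB genes 0.57 (5 and 3 of 23, and 5 and 3). Wnt targets gave 0.47, with 4 of 22 higher, LGR5, MYC, MSX1 and DKK1 (4 adjusted over the list alone). Mesenchymal genes gave 0.082, with 7 of 25 higher and TGFBI lower (7 and 1 adjusted over the list alone) at a median of 0.63, and VIM of this list was high in sgZ1 replicate 2 and sgZ3 replicate 3 alone (22.9 and 21.2 CPM). SnoRNA host genes gave 0.087 (8 and 1 of 23, and 8 and 1), histone genes 0.65 (1 and 0 of 16, and 0 and 0), and non-polyadenylated nuclear RNAs 0.63 (0 and 0 of 4, and 0 and 0). Markers of other cells gave 0.55 for fibroblasts (PRRX1 lower, of 6, while COL1A1 was at 12.2 CPM in sgZ1 replicate 2 and 15.2 CPM in sgZ3 replicate 3 against at most 1.4 CPM elsewhere), 0.55 for leukocytes (CSF1R lower, of 4), 0.90 for endothelium (ESAM higher, of 5) and 0.47 for embryonic kidney packaging cells (PAX2 higher, of 7, with 2 counts in sgC, 152 in sgZ1 and 4 in sgZ3, while in sgZ3 alone 0 were higher and 3 lower, 4 adjusted over the list alone), with the same counts over both guides adjusted over the list alone. The lower genes were ZCCHC7, ZCCHC8 and RBM7 (exosome), TAF1D, TOP2A and BAZ2A (RNA polymerase I, TAF1D also a snoRNA host), BBC3, TP53INP1, RRM2B and CCNG1 (p53), PCK2, FOXO1 and CREB1 (gluconeogenesis), ACACB and ACSS2 (fatty acids), RELB, BIRC3 and TRAF1 (NF-kappaB), and SLC7A11, AKR1C3 and ABCC3 (NRF2). Higher were G6PC3 and SLC37A4 (gluconeogenesis), BNIP3, SLC2A1 and CA12 (hypoxia), FASN, ACLY, ELOVL5 and FADS1 (fatty acids), TNFAIP2, CXCL1, CXCL2, CXCL3 and IER3 (NF-kappaB), PGD, ABCC2 and PRDX1 (NRF2) and H2BC12 (histones). These are calls for the mean of both guides. BNIP3 was higher in sgZ1 and lower in sgZ3. In sgZ3 alone FASN, ELOVL5, FADS1, TNFAIP2, IER3, ABCC2, TAF1D, ACSS2, RELB, AKR1C3, ABCC3, MYC, MSX1, DKK1, TGFBI and PAX2 were not called. In sgZ1 alone ZCCHC7, ZCCHC8, TOP2A, BAZ2A, BBC3, TP53INP1, RRM2B, FOXO1, CREB1, ACACB, TRAF1, G6PC3, SLC37A4, SLC2A1, CXCL1, CXCL2, CXCL3, PGD, H2BC12, LGR5, CSF1R and ESAM were not. The median, mean and test differed in sign for p53 targets, gluconeogenesis, fatty-acid synthesis, fibroblast and packaging-cell markers. The 13 mitochondrially encoded genes had 0 counts in all libraries and were not tested.

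With sgZ1 alone, 3807 genes passed the test against sgC (edgeR quasi-likelihood, Benjamini-Hochberg), 2286 higher and 1521 lower, and 950 changed at least 2-fold, 808 of them higher. Small-subunit factors rose in 38 of 60 (43 adjusted over the list alone, camera adjusted p = 1.8e-07), large-subunit factors in 28 of 53 (32; 1.6e-05) and MYC targets in 41 of 58 (44; 2.4e-10). Each of these lists had adjusted p = 0.14 with an estimated correlation. G1/S genes rose in 28 of 43 (32 adjusted over the list alone, camera adjusted p = 2.3e-08, adjusted p = 0.33 with an estimated correlation) and heat-shock genes in 15 of 23 (18; 1.6e-05, adjusted p = 0.15 with an estimated correlation). Immediate-early genes rose in 16 of 25 (17 adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.16 with an estimated correlation), with DUSP4 at 1.91 (SE 0.093) and FOSL1 at 1.56 (SE 0.13). Mitochondrial ribosome genes rose in 16 of 70 (16 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.96 with an estimated correlation). Interferon-stimulated genes fell in 7 of 35 (7 adjusted over the list alone, camera adjusted p = 0.0096, adjusted p = 0.39 with an estimated correlation) and epithelial adhesion genes in 12 of 27 (13; 0.018, adjusted p = 0.80 with an estimated correlation). Enterocyte genes fell in 5 of 19 (9 adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.48 with an estimated correlation), with LGALS4 at -1.39 (SE 0.18). The call of mitochondrial ribosome genes was lost without sgC replicate 3 (camera adjusted p = 0.092) or sgZ1 replicate 2 (0.35), that of epithelial (0.13) and enterocyte genes (0.067) without sgZ1 replicate 2, and that of interferon genes without sgZ1 replicate 1 (0.06). Against the direction of their lists, RIOK3 fell and CA2 and ESRP1 rose. The share of calls that were higher, 60%, was 35.5% with gene length and GC offsets. The libraries labelled sgZ1 also hold MSH6 at 67.3 to 74.8 CPM and DKK1 at 290 to 381 CPM. Without sgC replicate 1 or 3 the number of genes called was 2129 or 2466.

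With sgZ3 alone, 5355 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg), 2834 higher and 2521 lower, and 687 changed at least 2-fold, 508 of them lower. Ribosomal proteins rose in 33 of 47 for 60S (39 adjusted over the list alone, camera adjusted p = 6.9e-08) and in 18 of 33 for 40S (27; 5.5e-06), oxidative phosphorylation genes in 25 of 48 (33; 2.3e-06). Each of these 3 lists had adjusted p = 0.74 with an estimated correlation. Mitochondrial ribosome genes rose in 45 of 70 (46 adjusted over the list alone, camera adjusted p = 1.6e-10, adjusted p = 0.64 with an estimated correlation). MYC targets rose in 39 of 58 (40 adjusted over the list alone, camera adjusted p = 6.2e-15), small-subunit factors in 33 of 60 (35; 1.7e-07) and heat-shock genes in 16 of 23 (17; 6.9e-08), each with adjusted p = 0.094 with an estimated correlation. Large-subunit factors rose in 24 of 53 (26 adjusted over the list alone, camera adjusted p = 4e-05, adjusted p = 0.12 with an estimated correlation) and G1/S genes in 29 of 43 (30; 2.4e-12, adjusted p = 0.18 with an estimated correlation). Cholesterol genes rose in 13 of 25 (14 adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.43 with an estimated correlation) and translation factors in 20 of 42 (21; 0.0049, adjusted p = 0.58 with an estimated correlation). ATF4 and amino-acid stress genes fell in 16 of 32 (17 adjusted over the list alone, camera adjusted p = 1.7e-06, adjusted p = 0.26 with an estimated correlation), with VLDLR at -1.49 (SE 0.15) and SLC7A11 at -1.35 (SE 0.14). In sgZ3 replicate 3, VIM stood at 21.2 CPM. The non-polyadenylated RNAs RMRP and RPPH1 were highest in replicate 2 of each guide, RMRP at 12.4 CPM in sgC, 13.02 in sgZ1 and 85.5 in sgZ3 and RPPH1 at 9.75, 10.8 and 35.1 CPM, which may reflect poly(A) selection. The list of 4 such RNAs did not pass (median 3.63-fold, camera adjusted p = 0.44). Without sgC replicate 1 or 3, or sgZ3 replicate 1 or 2, the number of genes called was 3097, 3083, 3224 or 3080. The higher share, 52.9%, was 60.9% with gene length and GC offsets and 43.3% without sgZ1 replicate 2 and sgZ3 replicate 3. It was 41.5% with upper-quartile factors and 29.6% with library totals alone. The median log2 fold change of all tested genes was -0.173 with library totals alone and -0.0176 with TMM factors. With library totals alone each gene list called in sgZ3 kept its call and its direction. Camera compares list members with the other genes, so a scale change shared by all genes moves both alike. These kept calls therefore say little about the size or sign of the members' own fold changes. Against the direction of their lists, RIOK3, KRR1, SDAD1, RSL24D1, MRPS30, MTIF2, NDUFB5, PRIM1, STARD4 and EIF5 fell and ATF5, SLC3A2 and GDF15 rose.

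Both guides called 979 genes higher and 729 lower, 1708 in the same direction, and 148 in opposite directions. HAS3, SLC1A3, FKBP4, FEN1, TXNIP and PCK2 were among those called alike. Independent lists of these sizes would share 440 higher and 260 lower genes. Since both comparisons use the same sgC libraries, all 9 libraries, sgC included, were simulated without changes in 20 draws, with genes drawn independently. The simulated guide groups shared 0 calls against their common controls. Their fold changes correlated across genes at r = 0.493 (0.443 to 0.545) with a covariance of 0.0289 and agreed in sign for 66.6% of genes. Few calls arise without changes, so the 0 shared calls cannot show what differences particular to the real sgC libraries add. The observed correlation across genes, which are not independent replicates, was 0.355 (Spearman 0.483), with a covariance of 0.195 and 69.3% of genes alike in sign. The controls could not be split into groups of 2 libraries, so part of the excess may come from the shared controls. Without sgC replicate 1 or 3, 693 or 851 genes were called alike. The majority of higher genes among those called alike turned with library totals alone (703 higher, 1202 lower) and upper-quartile factors (819 and 984). It also turned with gene length and GC offsets (749 and 1147), with 7 libraries (1194 and 1418) and with a 2-fold minimum (48 and 65). The other settings kept it, barely so with fits of the compared groups only (979 and 978). Opposite calls numbered 43, 57 or 49 without sgC replicate 1, 2 or 3, 82 or 305 without sgZ1 replicate 1 or 2, 74, 63 or 300 without sgZ3 replicate 1, 2 or 3, and 463 with gene length and GC offsets. Without sgZ3 replicate 3 r was 0.0905. Without sgZ1 replicate 2 and sgZ3 replicate 3, 2612 genes were called alike and 946 opposite, and r was 0.0436. Each guide called more genes there, and independent lists of those sizes would share 787 higher and 816 lower genes.

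The guides also differed from each other. Between sgZ3 and sgZ1, 4209 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg), 1882 higher and 2327 lower in sgZ3, and of 1042 that differed at least 2-fold 959 were lower. REG4, a secreted lectin of intestinal cells (log2 difference 1.76, SE 0.24), C4BPB, a complement regulator (1.62, SE 0.15), LINC01508 (1.51), LRP11 (1.5) and CALCA, the calcitonin gene (1.41), were higher in sgZ3. The largest differences the other way were in genes close to absent from sgC and sgZ3. ANXA10, an annexin, was at 24.7 ± 2.57 CPM in sgZ1 (SD, n = 3), with 0 counts in sgC, which allows up to 0.0502 CPM over that group, and 3 counts in sgZ3. NTSR1, a neurotensin receptor, was at 58.0 ± 16.2 CPM with 7 and 8 counts, SLC38A5, an amino-acid transporter, at 44.5 ± 5.97 with 8 and 7, M1AP at 10.8 ± 0.851 with 1 and 0, and OR51B5 at 8.38 ± 0.883 with 1 and 1; such limits cover counting error only. Of the lists, ATF4 and amino-acid stress genes (camera adjusted p = 0.0011, adjusted p = 0.75 with an estimated correlation) and immediate-early genes (7.8e-07, adjusted p = 0.41 with an estimated correlation) were lower in sgZ3, in 14 of 32 and 17 of 25 genes (19 and 18 adjusted over the list alone). Cholesterol genes (0.00085) and the unfolded protein response (0.0053) were higher in sgZ3, in 14 of 25 and 12 of 25 genes (16 and 15 adjusted over the list alone), each with adjusted p = 0.75 with an estimated correlation. Respiratory chain genes (0.0011), 60S (0.0026), 40S (0.0032), mitochondrial ribosome (0.0038) and histone genes (0.005) were also higher as lists, in 6 of 48, 1 of 47, 1 of 33, 9 of 70 and 5 of 16 genes (0, 0, 0, 2 and 7 adjusted over the list alone), each with adjusted p = 0.92 with an estimated correlation. The histone call was lost without sgZ3 replicate 2 (camera adjusted p = 0.082), the library with RMRP at 85.5 CPM. Among genes against the direction of their lists, SLC3A2 and GDF15 were higher and ERN1, MVD, MRPS21 and MRPS30 lower in sgZ3. Without sgZ1 replicate 1, or sgZ3 replicate 1 or 2, 2501, 2690 or 2636 genes were called. The higher share, 44.7%, was 27% with library totals alone and 71.6% with gene length and GC offsets, so the majority depends on the scaling. The median log2 difference of all tested genes was -0.121 and 0.137 in these settings, against -0.0125 with TMM factors alone.

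No ribosomal RNA entry was called between both guides and sgC, in exact tests that could not call fewer than 5 of 20 entries. The ribosomal RNA libraries hold 48581516 to 74939039 estimated counts each over 20 ribosomal RNA entries, near-identical copies among which shared reads may have been divided. The 45S precursor entries, whose sequence includes the mature species, took 75.1 ± 0.23% of the counts in sgC (SD, n = 3), 74.6 ± 0.0481% in sgZ1 and 75.2 ± 0.12% in sgZ3. Reads of mature species may be counted in these entries, so their share does not measure precursor alone. Shares of a library's total also cannot show a change in the overall amount of ribosomal RNA. The 28S entries took 20.8 ± 0.451%, 21.3 ± 0.45% and 20.9 ± 0.148%, and 18S 3.83 ± 0.432%, 3.82 ± 0.289% and 3.73 ± 0.0731%. The 5.8S share was 0.275 ± 0.126% in sgC, 0.321 ± 0.208% in sgZ1 and 0.136 ± 0.0277% in sgZ3, and 5S had 0 to 13 counts. Over both guides 0 of 20 entries passed a two-sided exact permutation test on log2 shares (84 splits, smallest possible p = 0.012), 0 had an unadjusted p under 0.05, and the lowest p was 0.11 for RNA28SN1 (log2 difference 0.06; Benjamini-Hochberg adjusted p = 0.73). The edgeR quasi-likelihood test, which has no such limit, also called 0 entries. With 3 libraries against 3 the exact test cannot go below 0.1, so each guide alone could not reach 0.05. The other named entries, RNA45SN3, RNA45SN4, RNA5S9, RNA28SN2, RNA18SN5, RNA18SN1, RNA45SN5, RNA18SN4 and RNA5-8SN2, had adjusted p = 0.73 or more.

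**Figure D3:**
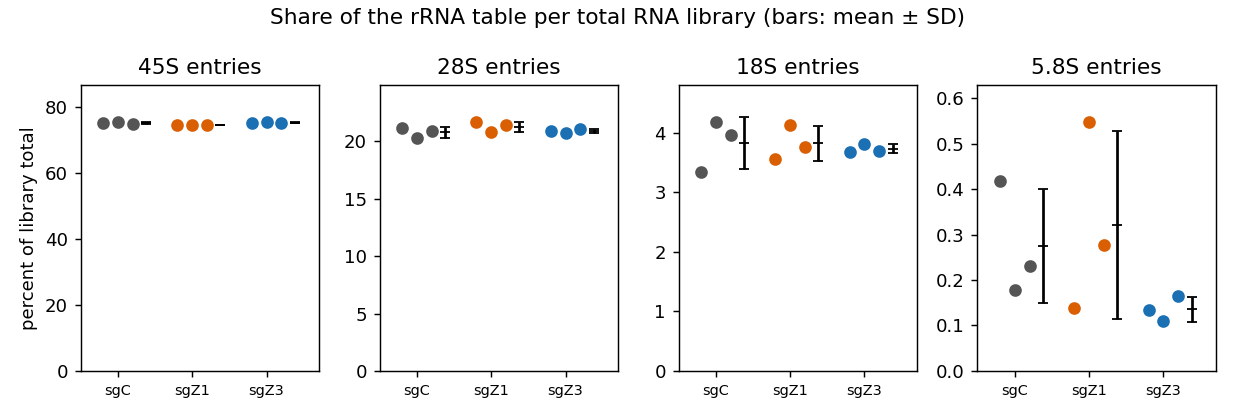
Share of each library's ribosomal RNA counts, in percent, taken by 45S, 28S, 18S and 5.8S entries, by guide; points are libraries, lines and bars the mean ± SD of 3. The 45S share lies between 74.5 and 75.3% in all 9 libraries.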

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

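The tests of the sgZ1 libraries, of the transcripts shared by 2 libraries and of the gene lists without sgZ1 were chosen only after the results were seen. The length and GC trend and the regroupings of libraries had their outcomes written down before those tests were run.

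The effect of the guides differed for 38 of 81 named genes and 9 lists, by the edgeR quasi-likelihood test (Benjamini-Hochberg) or camera on sgZ3 minus sgZ1. Genes higher with sgZ1 had log2 differences of -0.475 for ZNF692 (adjusted p = 0.025), -2.94 for MYL9, -4.56 for CPNE7, -2.92 for HAS3, -2.90 for PWP2, -1.66 for HS3ST1, -0.899 for RP11-660L16.2, -1.91 for STMN3, -0.616 for MVD, -2.14 for DUSP4, -1.02 for FOSL1 and -0.387 for CHORDC1 (SE 0.094 to 0.47). Genes below sgC over both guides and lower with sgZ3 than with sgZ1 had -0.875 for TXNIP, -0.754 for TCP11L2, -0.904 for DLX3, -0.403 for PSAT1, -0.832 for VLDLR, -0.827 for SLC7A11, -0.833 for IFIT2 and -0.35 for SPRED1. Genes higher with sgZ3 had 1.05 for SLC1A3, 1.76 for REG4, 1.62 for C4BPB, 1.51 for LINC01508, 1.5 for LRP11, 1.41 for CALCA, 0.448 for NOP16, 0.426 for RPL17, 0.654 for POLR3K, 0.326 for SLC19A1, 0.607 for DHCR7, 0.295 for HERC6 (adjusted p = 0.046) and 0.972 for LGALS4. The fitted values for M1AP (-10.8), ANXA10 (-8.62), NTSR1 (-8.52), OR51B5 (-8.39) and SLC38A5 (-8.33) rest on few or 0 counts outside sgZ1 and are no bounds.

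Median differences between guides were 0.285 for 40S and 0.235 for 60S ribosomal proteins, -0.405 for ATF4 and amino-acid stress genes, 0.249 for the unfolded protein response, 0.393 for cholesterol genes, 0.286 for oxidative phosphorylation, 0.228 for the mitochondrial ribosome, -0.507 for immediate-early genes and 0.805 for histone genes, with camera adjusted p from 7.8e-07 to 0.0053. All 9 of these list calls were lost with an estimated correlation, where adjusted p ran from 0.41 to 0.92.

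The first pattern is the 87 genes on in the 3 libraries labelled sgZ1 and off in all other poly(A) libraries. Of 124 genes on in sgZ1 and off in sgC, 0% were above 2 CPM in every sgZ3 library. The 87 genes are among these 124 and were chosen as off in sgZ3, so for them this outcome was fixed in advance. The share therefore cannot decide on loss of ZNF692 acting alike with both guides. The others of the 124 were free to pass, and 0% did. RNA from another cell line in these libraries is a candidate explanation: of the 184 genes that differed 4-fold or more from the other 6 libraries 0% fell, as a partial mixture would give, because the remaining DLD1 RNA limits any fall. A change within the DLD1 cells that carry guide 1 cannot be told apart from it, since the guide and any second source coincide; MSH6 was 9.25-fold higher in sgZ1 than in sgC.

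The second pattern is the set of 46 genes at least 8-fold higher in sgZ1 replicate 2 than in the other sgZ1 libraries. Of these, 95.7% were also at least 4-fold higher in sgZ3 replicate 3 than in the other sgZ3 libraries, against 0.517% of other genes above 2 CPM in sgZ3 replicate 3. RNA from a further cell source in both libraries may account for this, with VIM, SPARC and COL1A1 (12.2 and 15.2 CPM) in the set. The exceptions were CH507-513H4.3 and CH507-513H4.4, both highest in replicate 2 of each guide, as RMRP and RPPH1 were. CH507-513H4.3 stood there at 130 CPM in sgC, 339 in sgZ1 and 756 in sgZ3. Replicates of a guide share every label, so no biological explanation was tested.

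The third pattern is the rise of the small-subunit, large-subunit, MYC-target and G1/S lists, and of the ribosomal protein, oxidative phosphorylation and mitochondrial ribosome lists, over both guides. Fold changes over both guides correlated with gene length (r = -0.15) and GC content (r = 0.22) across genes. For length r was -0.23 in sgZ3 and -0.061 in sgZ1, and for GC content 0.16 and 0.19. Lists of the second group hold short genes, with median lengths of 2571.5 to 3527 bases against 4698 for all tested genes. With the length and GC trend removed, 4 of 4 lists of the first group and 4 of 4 of the second kept their direction over both guides. They also kept an adjusted p under 0.05 by camera at the preset correlation, which argues against the trend as the whole cause. With an estimated correlation and no offsets, adjusted p over both guides was 0.037 for 3 lists of the first group, 0.12 for G1/S genes and 0.66 to 0.71 for the second group. RNA in the sgZ1 libraries cannot account for the rise of the first group in sgZ3. There 4 of 4 lists kept their call at the preset correlation against sgC without those libraries. That comparison does not use the sgZ1 levels, and the lists had already passed in it, so the sgZ1 part of the rise stays undecided. With an estimated correlation no list passed in sgZ3 in the fit of all 9 libraries. An effect of losing ZNF692 stays open as a hypothesis, and so does grouping by luck. Of 100 groupings of the 9 libraries, 8 called at least 17 lists over both guides, a count that includes the real grouping with its 17. The other 99 called a median of 11 and at most 19, so chance cannot be excluded for that number.

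For the number of genes called over both guides, 1 of 100 regroupings of the 9 libraries, the real one, gave as many (4885, highest other 2969). For genes called alike by both guides it was also 1 of 100 (1708, highest other 850). The other regroupings mix libraries of different guides within groups, which widens the spread, and 92 of 99 called 0 genes over both guides. These counts thus show that libraries differ by label. They cannot tell an effect of the guides from chance differences between cultures or in handling. For single pairs of groups the 10 splits are too few for a share under 0.05. The real counts were 3807 for sgZ1, 5355 for sgZ3 and 4209 between guides, and the highest others 0, 0 and 1305.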

How the results depend on the processing

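The fits on 7 libraries, with length and GC offsets, without the sgZ1 libraries and over summed ribosomal RNA copies were chosen only after the results were seen. The majority of higher or lower calls turned with the scaling: over both guides 56% higher became 45.9% with upper-quartile factors, 36.6% with library totals alone, 47.7% with offsets and 46.5% with 7 libraries, for sgZ3 52.9% became 41.5% and 29.6% with upper-quartile factors and library totals and 43.3% with 7 libraries, and between guides 44.7% became 71.6% with offsets. Of the lists, Wnt targets between guides passed as a fall with 7 libraries (median -0.253, adjusted p = 0.018), while with all libraries camera gave an uncalled rise (adjusted p = 0.96) although the median was -0.0132. Where a value changed the cause was not tested unless the setting itself gives it. Stricter thresholds lowered the counts by construction. Counts are in the order both guides, sgZ1, sgZ3, between guides, and alike with both guides. A false discovery rate under 0.01 gave 2278, 2005, 2609, 2254 and 648 genes, and a 2-fold minimum 617, 950, 687, 1042 and 113. A mean of at least 10 CPM, which tests fewer genes, gave 2527 for sgZ1 and 2676 between guides. The 7 libraries gave 7409, 5894, 8246, 7932 and 2612. Length and GC offsets gave 6341 between guides (71.6% higher, with a median of 0.137 over all genes) and a higher share of 35.5% for sgZ1. Leaving out each library, with fewer samples, gave 2201 to 6337, 2129 to 4855, 3080 to 6796, 2501 to 6153 and 693 to 2311. DESeq2, RLE and upper-quartile factors, library totals, no low-count filter and fits of the compared groups only, which have no form for both guides together, kept these counts within 1.5 times.

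ZNF692 over both guides lost its call with library totals alone (log2 fold change 0.325) and with offsets (0.255), and ranged from 0.385 to 0.483 with each library left out.

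With an estimated correlation 4 lists were called over both guides and 0 in sgZ1, sgZ3 and between guides, and adjusted p rose to 0.71 for 40S, 60S and oxidative phosphorylation, 0.66 for mitochondrial ribosome, cholesterol and adhesion, 0.53 for translation factors, ATF4, interferon, enterocyte and immediate-early, 0.24 for RNA polymerase III and 0.12 for G1/S lists. Fry called 16 lists in sgZ1. Over both guides it lost 40S (0.16), 60S (0.12), oxidative phosphorylation (0.16), mitochondrial ribosome (0.052) and adhesion (0.085) and added the exosome (0.013) and glycolysis (0.013). The 7 libraries lost cholesterol (0.058) and enterocyte (0.066) lists and added snoRNA hosts (0.031). Offsets lost immediate-early genes (0.35) and added the exosome (0.011) and RNA polymerase I (0.039); library totals lost immediate-early (0.065) and added mesenchymal genes (0.024).

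With each library left out, the lists whose call over both guides changed had adjusted p from 0.014 to 0.08 (immediate-early), 0.017 to 0.14 (interferon), 0.032 to 0.23 (glycolysis), 0.013 to 0.23 (hypoxia), 0.013 to 0.12 (mesenchymal) and 0.012 to 0.28 (snoRNA hosts). Calls were also lost in sgZ1 for mitochondrial ribosome (up to 0.35), epithelial (0.13), enterocyte (0.067) and interferon lists (0.06), and between guides for histone genes (0.082). Calls were gained in sgZ1 for 60S (camera adjusted p down to 0.012), RNA polymerase I (0.028), translation factor (0.029) and mesenchymal lists (1e-07). They were gained in sgZ3 for histone (0.00067), snoRNA host (0.0047), mesenchymal (0.015), unfolded protein response (0.015), hypoxia (0.017) and RNA polymerase III lists (0.039). Between guides they were gained for mesenchymal (7.2e-06), RNA polymerase I (0.035), fatty-acid (0.035) and interferon lists (0.046).

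The replicate number as a block gave 5488, 4202, 5974, 5005 and 1996 genes, and added glycolysis (adjusted p = 0.049). Same-numbered libraries correlated over 0.1 in 3 of 9 pairs (-0.12 to 0.25), and 4 of 9 libraries correlated best with their own number, so the numbers were not taken to pair samples. RMRP, RPPH1, SCARNA2, CH507-513H4.3 and CH507-513H4.4 were highest in replicate 2 of each guide (SCARNA2 1.5, 4.05 and 7.43 CPM). Shared handling of same-numbered libraries is therefore not excluded. CPA4 lost its call under the block (adjusted p = 0.065).

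Of 80 named gene results 8 lost a call in some setting. For these genes DESeq2, the false discovery rate under 0.01, the 2-fold minimum and fits of the compared groups only were not counted. The mean of at least 10 CPM covered 55 of the 80. For ribosomal RNA shares the exact tests called 0 entries, but a single entry could not pass after adjustment in the settings run with them (smallest adjusted p 0.24 for 20 entries, 0.06 for 5 summed species), so these counts say nothing about stability. EdgeR also called 0 entries (lowest adjusted p = 0.73). In the self-test for both guides 44.8% of 1.5-fold changes were recovered.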

Other observations

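The levels below were chosen after the values were seen. CDKN2A, which encodes the cell-cycle inhibitor p16, stood at 1.80 to 3.16 CPM in sgC, 32.3 to 36.9 CPM in sgZ1 and 0.705 to 1.22 CPM in sgZ3. LGALS1, galectin-1, stood at 16.9 to 24.6, 110 to 133 and 20.6 to 30.1 CPM, and CAV1, caveolin-1, at 35.7 to 38.2, 163 to 187 and 47.9 to 51.9 CPM. MSN, moesin, stood at 5.97 to 7.66 CPM in sgC and 94.6 to 108 CPM in sgZ1, and at 36.9 CPM in sgZ3 replicate 3 against 2.98 and 2.06 CPM in the other sgZ3 libraries.

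In a principal component analysis of the 9 poly(A) libraries, component 1 held 58.5% of the variance and set the libraries labelled sgZ1 (57.1 to 64.9) apart from sgC (-27.2 to -26.6) and sgZ3 (-44.0 to -16.5). Component 2 held 21.4%.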
